A study of Arabidopsis thaliana with 20 samples.

How the data were processed

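Transcript levels were measured in 20 whole-seedling samples of Arabidopsis thaliana on Affymetrix one-colour arrays holding 22746 probe sets. Per the labels' protocols, seedlings were grown for 10 days on agar at 23 °C with 16 h of light a day, then kept in cycloheximide (CHX) for 2 h and in CHX with or without dexamethasone (DEX) for 4 h more. Those protocols give 10 µM for both compounds, while other label fields give 10 mM, and this conflict was left open. Biotin-labelled cRNA was made from 10 µg of RNA. Each sample's line and treatment were taken from its label, which gave 4 groups of 5 arrays. No label says whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

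Signals were computed with MAS5, per the submitters' processing notes, which give no version. The deposited values were on a natural log scale, which was worked out from the values themselves: each column's median was 0, and after exponentiation every array returned to whole multiples of a single step. That held for 100% of the values checked per array (13798 to 14327 values under 3000 steps, tolerance 0.02 of a step), and the step was taken as the 0.1 in which MAS5 signals are written. On that scale the trimmed mean, leaving out 2% at each end, was 495.8 to 496.4 on every array, the median was 159.7 to 186, and the maximum 23445 to 32426. The deposited values were thus natural logs of the signal divided by its array's median. They were turned into log2 for the tests, and the signals printed are those recovered in this way. Detection calls were not used here. Signals of a few units lie near the floor of the scale and carry no reliable ratio. The number of arrays limits the precision of every value. All 22746 probe sets were tested, and 0 of them were AFFX controls. No columns were left unused.

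Probe sets were named through the table of the array's genes supplied for this work, with symbols from RefSeq (assembly TAIR10.1, used for names alone). A single gene was matched for 13436 probe sets (59.1%, 13286 genes), 503 were paired with several genes, 77 had 1 gene that was not matched, and 8730 were not listed. A probe set without a single matched gene is called unnamed. No probe set was paired with VND7 itself, so its level in each sample is not analysed here. Where a gene had several probe sets, the one with the highest mean over the 20 arrays stood for it in gene lists. No coordinates are printed, since the build behind the probe sets is not given in the sources used here.

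Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend) on 4 group means over all 20 arrays. Benjamini-Hochberg adjusted p under 0.05 was the threshold. The contrasts were the DEX response in each line (DEX with CHX against CHX alone), the difference between the responses of the lines, and the difference between the lines under CHX alone. An induced set held probe sets that passed in the line with the VND7 fusion with a rise of at least 2-fold, passed upwards in the difference of responses and did not pass upwards in the empty-vector line. Calls shared by both lines were compared with the number given by independent lists, with a two-sided Fisher's exact test. That test used the rises alone. The design set a pseudocount for a linear table and none for a table on a log scale, so none was used. All adjusted p-values for genes are limma's, and all n are 5 arrays per group.

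The groups, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. Named genes were those with the 14 largest rises and 8 largest falls past the threshold in the VND7 line, the 6 largest rises and falls likewise in each other contrast, and up to 4 members of each fixed list with the smallest adjusted p. Genes outside that rule are said to be so where they appear. The 19 fixed lists held 261 genes, of which 37 had a named probe set. Lists with at least 3 measured members (7 of them) were tested with camera at a preset inter-gene correlation of 0.01, adjusted over lists, then again with an estimated correlation, and with fry, which passed 0 fixed lists in any comparison. In 4 lists no member had a named probe set: secondary wall cellulose, the VND and NST genes, phloem and endodermis. A further 21 lists were added after the data had been opened and before any test was run, and were adjusted among themselves.

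Replicate numbers in the labels were read as pairing arrays if every correlation below exceeded 0.1, a criterion that uses no calls. The correlations and the calls with and without the block were first computed in the same step. Over probe sets above the array median (11367), deviations from group means correlated between same-numbered arrays of different groups in each of 30 pairs (r = 0.558 to 0.835, median 0.746, across probe sets, which are not independent replicates). For replicates 2 with 3 and 4 with 5 the median was 0.69, and for other number pairs it was -0.394. The numbers were therefore read as pairing the arrays, and the arrays as falling into 3 batches: replicate 1, replicates 2 and 3, and replicates 4 and 5. The batches were found in the data and hold every group. Values from a fit with the replicate number as a block, and values within batches, are given beside the results they change. The fit without the block leaves differences between batches in the spread, so a count of 0 falls there does not show that none fell. Sets called on all arrays were selected on the arrays of each batch too, so their sign within batches is not separate evidence.

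Alternatives chosen in advance were a pseudocount at the 1st or 30th percentile of the signals, quantile normalization, centring on brighter probe sets, leaving out the dimmest 40% of probe sets, the compared arrays alone, the replicate block, no variance trend, a robust variance, array weights, and each array left out in turn. The fits with an array left out had no replicate block. For the lists an estimated correlation was also chosen, and for the induced set no minimum fold, or exclusion of empty-vector calls without the test of the difference. Alternatives added after seeing the data were a 10th-percentile pseudocount, the MAS5 scaling without division by the array median, a batch term, and the replicate block with the dim-probe filter.

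The limma steps were tested on simulated data with the 22746 probe sets and the spread of these arrays, for the DEX response in the VND7 line. Of 100 probe sets changed by 1 on the log2 scale 53 were recovered (43 of 58 among the brighter probe sets), and of 100 changed by 2, 68 were recovered (49 of 51 among the brighter). There were 6 false calls among 127, and 0 calls in a contrast left unchanged. The simulated noise was independent between probe sets and between arrays, without batches or pairing. These counts therefore do not measure recovery or false calls under the batches of the real arrays. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.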

Results

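Transcripts were measured in 10-day-old whole Arabidopsis seedlings of 2 lines. One carries 35S:VND7-VP16-GR, a single homozygous insertion that expresses VND7, a NAC transcription factor of xylem vessel differentiation, fused to the VP16 activation domain and to the hormone-binding domain of the glucocorticoid receptor. The other is an empty-vector line with the same fusion parts without VND7. DEX lets a protein fused to this receptor domain enter the nucleus, and CHX blocks protein synthesis. Each line was treated with CHX alone or with DEX and CHX, with 5 arrays per group. The design asks which genes respond to the fusion protein without new protein synthesis, with the empty-vector line as the control without VND7. Arrays of one group correlated with a median r of 0.929 across probe sets (lowest 0.911), and the first 2 principal components held 42.5% and 23.1% of the variance.

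**Figure D1:**
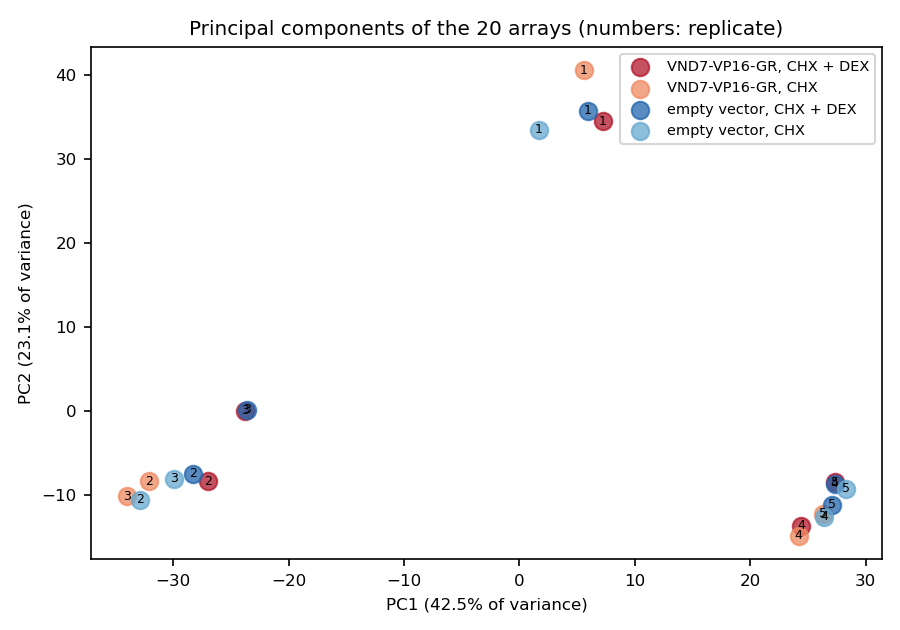
Principal components 1 and 2 of the log2 signals of the 20 arrays (42.5% and 23.1% of the variance), each point an array, with its group shown by colour and its replicate number on it. Arrays lie by replicate number more than by group: replicate 1, replicates 2 and 3, and replicates 4 and 5 form 3 clusters that each hold all 4 groups.

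In seedlings with the VND7 fusion, with DEX in the presence of CHX, AT1G70500, of the polygalacturonase family of pectin-cleaving enzymes, rose 8.81-fold, from a signal of 632 ± 202 to 5580 ± 1470 (SD, n = 5; log2 change 3.14 ± 0.25, SE, adjusted p = 3.649e-07). A relative, AT1G23460, rose 7.79-fold, from 354 ± 19.8 to 2880 ± 835 (log2 change 2.96 ± 0.19, adjusted p = 3.301e-08). Its probe set is of a type that can also bind related transcripts. AT3G47400, of the pectin methylesterase family, rose from 61.3 ± 17.5 to 478 ± 263 (log2 change 2.86 ± 0.29, adjusted p = 1.123e-05). AT5G38610, of the family of invertase and pectin methylesterase inhibitors, rose from 210 ± 42.1 to 1310 ± 365 (2.59 ± 0.20, adjusted p = 2.889e-07). PRX72, a peroxidase of lignin formation and a member of a fixed list, rose from 690 ± 189 to 1590 ± 323 (1.202 ± 0.18, adjusted p = 0.0007296).

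The largest rise among named genes was that of AT5G40020, a thaumatin family member, which went from 81.6 ± 14.9 to 876 ± 361 (log2 change 3.33 ± 0.52, adjusted p = 0.001492). That rank depended on the processing: over the alternatives its log2 change went down to 2.70, and that of AT1G70500 to no less than 3.02. AT5G44630, a sesquiterpene synthase, rose from 2.88 ± 1.59 to 27.9 ± 16.4 (adjusted p = 0.01682), from a base at the floor of the scale, so that the size of its log2 change was not settled (3.23 ± 0.63, or 0.51 with the 30th-percentile pseudocount). AT2G45040, a matrix metalloproteinase, rose by 2.71 ± 0.52 and AT4G18450, an AP2/ERF transcription factor, by 2.68 ± 0.52 (adjusted p = 0.0139 and 0.01778). The other genes named by the rule were AT1G24600 (2.88 ± 0.46), AT1G63520 (2.59 ± 0.51), AT5G60720 (2.27 ± 0.23), AT1G10800 (2.24 ± 0.47), AT5G19870 (2.17 ± 0.32) and AT3G52900 (2.15 ± 0.25), with adjusted p of 0.002064, 0.01768, 1.123e-05, 0.03109, 0.0008529 and 4.457e-05. With that pseudocount the log2 change was also smaller by over 1.5 times for AT1G24600 (1.57), AT2G45040 (1.56), AT4G18450 (1.57), AT1G63520 (1.63), AT1G10800 (1.46) and AT5G19870 (1.39), each still past the threshold. Each of these 14 genes was higher with DEX in 5 of 5 same-numbered pairs, which their selection on these same arrays favours.

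In all, 103 probe sets rose in this line and 0 fell (limma, adjusted p under 0.05; 53 of the 103 named; 82 by at least 2-fold). Unadjusted p under 0.05 was reached by 782 probe sets, 543 up and 239 down, where 1137 are given by chance; with the replicate number as a block it was 1788, 892 up and 896 down. The median rise of the 103 was 1.75 on the log2 scale (quartiles 1.13 and 2.20). With the replicate number as a block 211 rose and 25 fell, with all 103 among the rises. Without the block, differences between batches are part of the spread, so the 0 falls do not show that no transcript fell. Within batches the median change of the 103 was 2.18 in replicate 1, 1.72 in replicates 2 and 3, and 1.28 in replicates 4 and 5, with 103 of 103 positive in each. The 103 were selected on these same arrays, which favours that sign. For probe sets selected without a replicate, the median change in that replicate was 1.385 to 2.272. Without the DEX array of replicate 1 the count was 64, and without that of replicate 3 it was 67. These counts, and the calls lost below, come from fits without the block. AT1G10800 lost its call without any 1 of the 10 arrays of the line (adjusted p = 0.0514 to 0.114). With the block on all arrays its limma adjusted p was 0.01274. AT5G44630 lost it without the CHX array of replicate 3 (0.0539) or the DEX array of replicate 1 (0.0786), and AT2G45040 without the DEX array of replicate 1 (0.063) or 3 (0.0529). AT1G63520 lost it without the DEX array of replicate 1, 2 or 3 or the CHX array of replicate 3 (0.0515 to 0.0745), and AT4G18450 without the DEX array of replicate 1, 2 or 3 or the CHX array of replicate 5 (0.0513 to 0.0687).

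**Figure D2:**
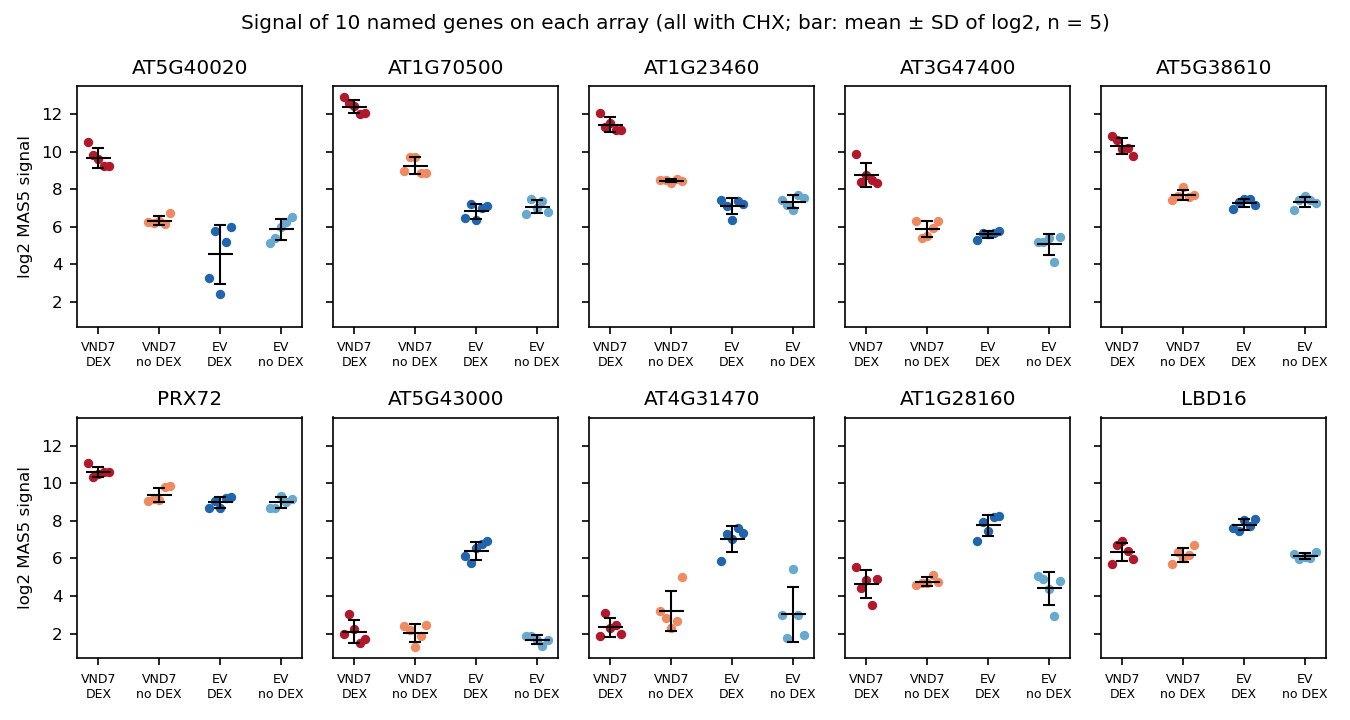
Log2 of the recovered MAS5 signal of 10 named genes (y axis) on each of the 20 arrays, by group (x axis; EV, empty vector), with points for arrays, horizontal marks for group means and bars for 1 SD of the log2 values. On the linear scale AT1G70500 averaged 5580 with DEX in the VND7 fusion line against 632 without it, and 117 and 138 in the empty-vector line with and without DEX.

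Of the lists fixed in advance, lignin genes shifted upwards in this line by camera (adjusted p = 0.01506; adjusted p = 0.0994 with an estimated correlation), but not by fry (adjusted p = 0.08924). PRX72 was the 1 of 4 measured members that rose, over all probe sets and also when adjusted over the list alone. HCT, of monolignol synthesis, had a log2 change of 0.13 ± 0.27, and the peroxidases PRX66 and PRX52 had 0.045 ± 0.21 and 0.02 ± 0.37. Of the list's 26 genes only these 4 had a named probe set. The list's median was 0.087 and its mean 0.349. With the block its adjusted p was 0.02378. Within batches the list's mean was 0.70, 0.35 and 0.17 and its median 0.46, 0.08 and -0.02, so the median was below 0 in replicates 4 and 5. The call was lost without the DEX array of replicate 2 (adjusted p = 0.08859) or 3 (0.05973), or the CHX array of replicate 1 (0.1172).

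Xylan genes did not pass (camera adjusted p = 0.2471; 0 of 4 measured members past the threshold, 0 adjusted over the list alone): the xylan synthases IRX10 and IRX10-L had log2 changes of 0.41 ± 0.16 and 0.01 ± 0.11, and IRX15 and IRX15-L had 0.89 ± 0.74 and -0.24 ± 0.65. Of the 22 xylan genes only these 4 had a named probe set, so the list as a whole was not examined. The lists below were also measured only in part. In the lists below, too, 0 members passed, over all probe sets or adjusted over the list alone (limma). Procambium genes (4 measured, adjusted p = 0.7497) included CLE41 at -0.07 ± 0.22, CLE44 at -0.07 ± 0.18, PHV at 0.00 ± 0.16 and LHW at -0.07 ± 0.12. Among epidermis and guard cell markers (3 measured, adjusted p = 0.2586) SPCH was at -0.48 ± 0.44, MUTE at -0.17 ± 0.77 and FAMA at -0.285 ± 0.21. Detoxification genes (3 measured, adjusted p = 0.99) had GSTU25 at 0.05 ± 0.22, UGT73B5 at -0.05 ± 0.16 and UGT73B4 at 0.005 ± 0.15. Early auxin genes (5 measured, adjusted p = 0.697) had LBD29 at -0.58 ± 0.63, GH3.3 at -0.26 ± 0.16, LBD16 at 0.12 ± 0.23 and IAA29 at 0.03 ± 0.22. Reference genes (3 measured, adjusted p = 0.7722) had GAPC2 at -0.06 ± 0.11, TIP41L at -0.08 ± 0.14 and SAND at 0.05 ± 0.12.

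Lists with 1 or 2 measured members were not tested as lists, and no measured member passed. Only 1 of 9 programmed cell death genes and 1 of 26 secondary wall transcription factors were measured. These values therefore do not show whether those groups of genes responded. For primary wall cellulose COB had a log2 change of -0.095 ± 0.36, for programmed cell death GAMMA-VPE had 0.04 ± 0.18, for secondary wall transcription factors C3H14 had 0.18 ± 0.28, and for wall patterning KINESIN-13A had 0.14 ± 0.11. For photosynthesis RCA had -0.12 ± 0.14 and LHCB4.1 had -0.085 ± 0.15. For root hairs EXPA7 had 0.05 ± 0.58 and EXPA18 had -0.15 ± 0.28. For defence PDF1.2 had 0.17 ± 1.07, and for rapid stress and touch WRKY53 had -0.04 ± 0.29 and ZAT10 had -0.045 ± 0.13.

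In the empty-vector line AT5G43000 rose with DEX from 3.24 ± 0.50 to 89.1 ± 27.7 (SD, n = 5; adjusted p = 1.241e-06), from a base at the floor of the scale, so that the size of its log2 change was not settled (4.73 ± 0.38, or 1.31 with the 30th-percentile pseudocount). AT1G28160, an AP2/ERF transcription factor, rose 10.2-fold, from 23.8 ± 10.2 to 230 ± 80.8 (3.35 ± 0.40, adjusted p = 8.584e-05), and AT4G31470, of the CAP family that includes PR-1, rose from 13.3 ± 17 to 142 ± 53 (4.01 ± 0.61, adjusted p = 0.001481). AT3G08490 rose by 4.27 ± 0.63, AT3G03230 by 2.95 ± 0.50 and AT4G17860 by 2.80 ± 0.57 (adjusted p = 0.001198, 0.004576 and 0.03213). With that pseudocount the log2 changes were 1.84 for AT1G28160, 1.53 for AT4G31470, 1.89 for AT3G08490, 1.58 for AT3G03230 and 1.26 for AT4G17860, each still past the threshold. LBD16, an auxin-induced gene of lateral root initiation, rose 3.14-fold, from 70.7 ± 7.23 to 225 ± 43.7 (1.65 ± 0.23, adjusted p = 0.0005457), and was the 1 of 5 early auxin genes to pass, also when adjusted over the list alone (camera adjusted p = 0.5596 for the list). All 7 genes were higher in 5 of 5 pairs, which their selection on these same arrays favours.

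In this line 64 probe sets rose and 0 fell (limma; 33 of the 64 named; 56 by at least 2-fold), and 832 had unadjusted p under 0.05, 551 up and 281 down (1901 with the block, 1031 up and 870 down). Their median rise was 1.69 on the log2 scale. With the block 150 rose and 12 fell, with all 64 among the rises. Within batches the median was 1.36, 1.53 and 2.02, with 64 of 64 positive in each, a sign that selection on these same arrays favours. AT4G17860 lost its call without the CHX array of replicate 1, 2, 4 or 5 or the DEX array of replicate 1, 2, 4 or 5 (adjusted p = 0.0599 to 0.127). Those fits had no block, and with the block on all arrays its limma adjusted p was 0.0224. The other fixed lists did not pass (smallest camera adjusted p = 0.5596, shared with procambium), and 0 of their members passed.

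A single unnamed probe set rose in both lines, by 1.84 ± 0.19 on the log2 scale with the VND7 fusion and 1.12 ± 0.19 with the empty vector. Independent lists of these sizes share 0.29 (two-sided Fisher's exact p = 0.2524). With the block 2 were shared upwards, 3 downwards and 2 were called in opposite directions (1.39 expected upwards, two-sided Fisher's exact p = 0.4063 for the rises alone). The 3 shared falls, of 25 with the VND7 fusion and 12 with the empty vector, were not tested. Among them were AT1G33811 (log2 changes -0.645 with the VND7 fusion and -0.706 with the empty vector) and AT5G26010 (-0.493 and -0.615). With the block and without the dimmest 40% of probe sets, an alternative chosen after seeing the data, 8 were shared, 5 upwards and 3 downwards, and the exact p for those upwards was 0.03315. Without the CHX array of replicate 1 of the VND7 fusion line 2 were shared and the exact p was 0.02536. The 103 probe sets raised with the VND7 fusion had a median log2 change of -0.02 in the empty-vector line, with 50 positive. The 64 raised in the empty-vector line had a median of -0.06 in the VND7 fusion line, with 24 positive.

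**Figure D3:**
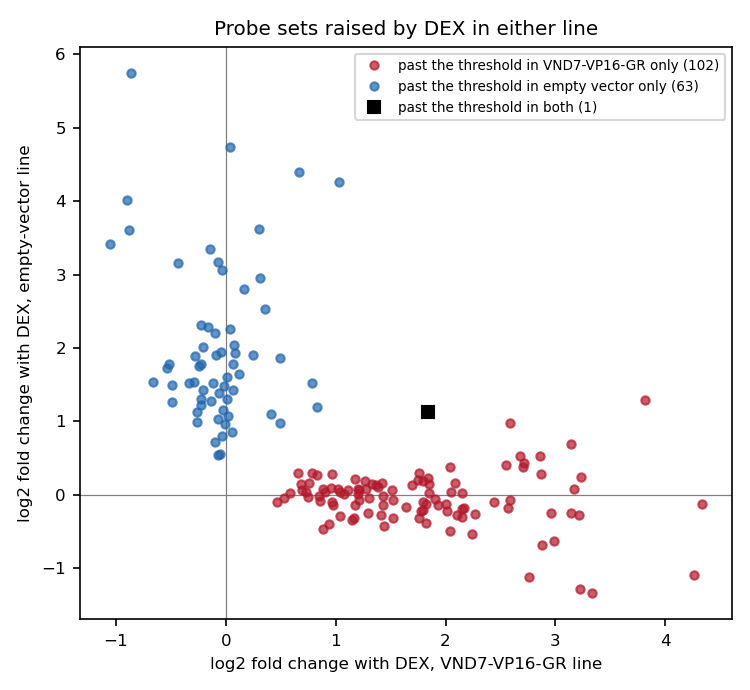
Log2 change with DEX in the VND7-VP16-GR line (x axis) against that in the empty-vector line (y axis) for the 166 probe sets that rose in either line, with colours for those that rose in one line and a square for the one that rose in both. The 102 that passed in the VND7-VP16-GR line and not in the other spread along the x axis, the 63 that passed in the empty-vector line and not in the other along the y axis, and 1 passed in both.

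The direct test of the difference between the 2 responses was passed upwards by AT5G40020 (difference of log2 changes 4.67 ± 0.73, adjusted p = 0.002534), AT5G44630 (4.51 ± 0.88, 0.01904), AT1G24600 (3.56 ± 0.65, 0.009971), AT1G70500 (3.38 ± 0.36, 5.916e-05), AT1G23460 (3.203 ± 0.27, 4.237e-06) and AT5G38610 (2.66 ± 0.29, 5.916e-05). It was passed downwards by AT4G31470 (-4.91 ± 0.86, 0.006763), AT5G43000 (-4.69 ± 0.53, 9.014e-05), AT1G28160 (-3.49 ± 0.56, 0.002862), the microtubule-associated protein gene AT3G23090 (-2.30 ± 0.29, 0.0002768), AT1G15640 (-2.27 ± 0.37, 0.003141) and AT2G17060, a resistance-type receptor gene (-4.12 ± 0.86, 0.03127). AT2G17060 passed in neither line alone, with log2 changes of -2.29 ± 0.61 with the VND7 fusion and 1.83 ± 0.61 with the empty vector, at signals of 5.74 to 41.3. With the block its change in the VND7 fusion line did pass (adjusted p = 0.01571). Low signals leave the size of several of these differences unsettled: with the 30th-percentile pseudocount they were 0.61 for AT5G44630 (adjusted p = 0.0552, so that its call was lost), 1.77 for AT1G24600, -1.67 for AT4G31470, -1.30 for AT5G43000, -1.85 for AT1G28160 and -0.87 for AT2G17060. Over all alternatives the difference for AT5G40020 went down to 3.14. PRX72 was higher by 1.195 ± 0.25 (adjusted p = 0.03063) and LBD16 lower by a difference of -1.53 ± 0.32 (0.03119). Lignin genes passed as a list (camera adjusted p = 0.03516; adjusted p = 0.1607 with an estimated correlation; 0.1539 by fry; 1 of 4 up, also when adjusted over the list alone; 0.02861 with the block), with means of 0.31, 0.66 and 0.10 within batches.

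Of the 103 probe sets raised with the VND7 fusion 49 passed this test upwards, and of the 64 raised with the empty vector 37 passed it downwards. AT1G10800 (adjusted p = 0.09922), AT2G45040 (0.5102), AT4G18450 (0.6194) and AT1G63520 (1), raised with the VND7 fusion, did not pass, nor did AT3G03230 (0.2085), AT3G08490 (0.2425) and AT4G17860 (0.425), raised with the empty vector. With the block AT1G10800 passed (0.03827). In all 51 probe sets were higher and 38 lower in the difference (limma; 27 and 23 named), and 121 and 118 with the block, which included these 51 and 38. Within batches the median was 2.80, 2.17 and 1.75 for the 51 and -1.83, -2.03 and -2.36 for the 38. Both sets were selected on these same arrays, which favours those signs. AT5G44630 lost this call without the DEX array of replicate 1 of the VND7 fusion line (0.0524). AT2G17060 lost it without any 1 of 13 of the 20 arrays (0.0532 to 0.0799): the empty-vector arrays of CHX replicates 2 and 3 and DEX replicates 1, 3, 4 and 5, and the VND7 fusion arrays of CHX replicates 1, 4 and 5 and DEX replicates 1, 2, 3 and 4.

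The set raised at least 2-fold with the VND7 fusion, higher in the difference and not raised in the empty-vector line held 45 probe sets (24 named), of the 82 that rose at least 2-fold. AT1G70500, AT1G23460, AT3G47400, AT5G38610, AT5G40020 and PRX72 were in it. Its median log2 change was 2.104 with the VND7 fusion and -0.19 with the empty vector. With the block it held 84 (40 named), which included all 45. Without the test of the difference, leaving out empty-vector calls alone, it held 81.

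Without DEX, AT1G70500 was 4.56-fold higher in the VND7 fusion line than in the empty-vector line (632 ± 202 against 138 ± 32.9; log2 difference 2.19 ± 0.25, adjusted p = 0.0002078), and AT1G23460 was 2.19-fold higher (354 ± 19.8 against 166 ± 35.9; 1.13 ± 0.19, 0.03443). AT2G04850, of a family of auxin-responsive membrane proteins, was 4.55-fold higher (450 ± 20.1 against 104 ± 32.9; 2.19 ± 0.21, 1.337e-05), and rose further with DEX, by 1.83 ± 0.21. Each was higher in 5 of 5 pairs, which selection on these same arrays favours. Of the other 3 probe sets that passed, none has a gene in the table used. The one with the largest difference was at 5880 ± 1520 against 30 ± 8.88, a low base (log2 difference 7.65 ± 0.25, or 6.15 with the 30th-percentile pseudocount), and the others were higher by 2.63 ± 0.22 and 1.22 ± 0.15 on the log2 scale. Fixed lists did not pass (smallest camera adjusted p = 0.4608).

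In this comparison 6 probe sets were higher and 0 lower (limma), and 607 had unadjusted p under 0.05, 321 up and 286 down (1636 with the block, 840 up and 796 down). With the block 18 were higher and 3 lower, which included these 6. Within batches the median of the 6 was 2.05, 2.51 and 1.93, with 6 of 6 positive in each, though the 6 were selected on these same arrays. AT1G23460 lost its call without any 1 of the 10 arrays except the empty-vector array of replicate 4 (adjusted p = 0.0762 to 0.152), without the variance trend (0.09102), and with the recovered MAS5 scaling (0.0718). Over all alternatives its adjusted p was 0.0008457 to 0.1515. The fits with an array left out had no block, and with the block on all arrays its limma adjusted p was 0.002733. The 103 probe sets raised by DEX with the VND7 fusion had a median line difference without DEX of 0.26, with 84 of 103 positive and 4 past the threshold.

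**Figure D4:**
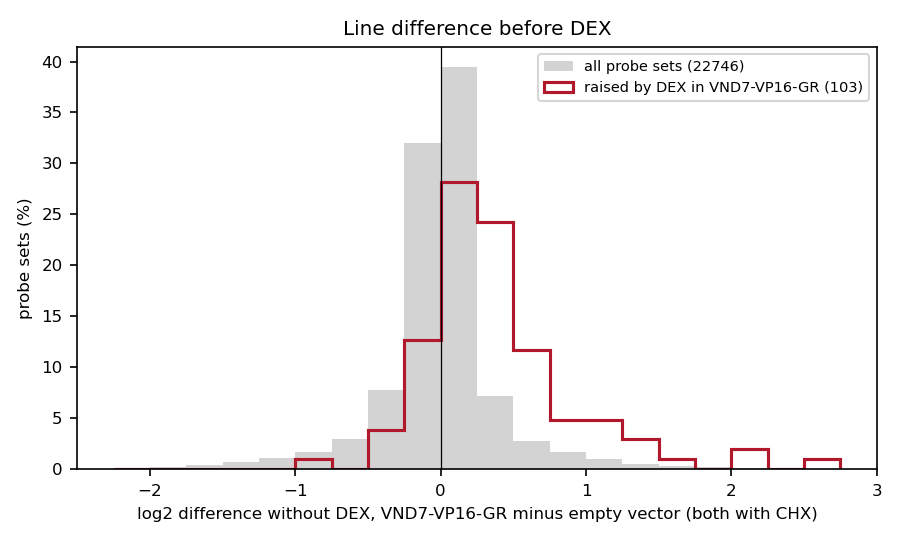
Distribution of the log2 difference between the lines under CHX alone (VND7-VP16-GR minus empty vector) (x axis), as the percent of probe sets in each bin (y axis), for all 22746 probe sets (grey) and for the 103 raised by DEX in the VND7-VP16-GR line (outline). The 103 have a median of 0.26, and the bins run from -2.25 to 2.75, which leaves out 23 of all probe sets and 2 of the 103.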

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

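Of the tests in this part, those on the 2 patterns weighed below were chosen after the result was seen; the counts over other splits of the arrays were planned, except the swaps of the lines within replicates. Single arrays stood apart from the other 4 of their group in 21 of 244 groups of named genes, where chance gives about 1 in 20 (12.2). Replicate 1 held 11 of them and replicate 2 held 4, with 2 each in replicates 3, 4 and 5. The value of 12.2 takes the arrays of a group as alike. Replicate 1 is a batch of its own, so an array of it can stand apart with its batch. GSTU25 was flagged as low in replicate 1 in 3 groups: 6760 in EV_CHX (others 10700 to 13100), 7230 in EV_DEX_CHX (11300 to 12700) and 8090 in VND7_DEX_CHX (12100 to 13700). In VND7_CHX replicate 1 it was lower too, at 7653 (others 11150 to 13340), without being flagged. LBD29 was low in replicate 1 in VND7_CHX (20.2; others 82.7 to 125) and VND7_DEX_CHX (6.4; 55.6 to 122). In EV_CHX replicate 1, SPCH was 51 (others 119 to 169), AT5G44630 21.4 (2.5 to 3.6) and CLE44 196 (142 to 155). Also in replicate 1, WRKY53 was 2650 in VND7_CHX (others 963 to 1390), AT5G60720 564 in VND7_DEX_CHX (243 to 285) and AT3G47400 39.6 in EV_DEX_CHX (49.3 to 54.3).

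In EV_DEX_CHX replicate 2, AT5G19870 was 18.1 (others 34.5 to 40.5), AT2G17060 23 (42.7 to 48.5), AT1G24600 7.3 (21.7 to 27.8) and GAPC2 13300 (11100 to 12200). In EV_CHX replicate 4, AT3G47400 was 17.4 (36.1 to 44) and AT1G28160 7.6 (20.7 to 33.3). AT5G19870 was 22.7 in VND7_CHX replicate 3 (47 to 55.4), AT1G23460 82.8 in EV_DEX_CHX replicate 3 (141 to 175), AT4G18450 2.4 in EV_CHX replicate 5 (13.2 to 29.7) and EXPA7 3 in EV_DEX_CHX replicate 5 (38.6 to 69.3).

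The responses to DEX differed between the lines for 89 probe sets by the test of the difference, among them 19 named genes. The difference of log2 changes was 4.67 for AT5G40020, 4.51 for AT5G44630, 3.56 for AT1G24600, 3.38 for AT1G70500, 3.203 for AT1G23460, 2.66 for AT5G38610, 2.53 for AT5G60720, 2.46 for AT3G52900, 2.34 for AT5G19870, 2.33 for AT3G47400, 2.21 for AT2G04850 and 1.195 for PRX72. It was -1.53 for LBD16, -2.27 for AT1G15640, -2.30 for AT3G23090, -3.49 for AT1G28160, -4.12 for AT2G17060, -4.69 for AT5G43000 and -4.91 for AT4G31470.

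Over splits of the arrays that ignore the pairing, 1 of 100 splits (the real one) called as many for the DEX response with the VND7 fusion (103, highest other 1) and with the empty vector (64, highest other 3), and 2 of 100 called at least the real 89 for the difference of responses and the real 6 for the lines under CHX alone. The other split for the difference called 4085, several times the real count, with most arrays of replicates 1, 4 and 5 on one side, and that for the lines called 292, with the arrays of replicates 2 and 3 and 1 of replicate 1 against the rest. Both follow the batches, and point to a structure of the samples, so these splits do not by themselves exclude chance for paired arrays. The splits for the difference also moved the DEX labels within each line. They test for a response in either line, so they cannot decide on the difference. With the block, 16 splits that keep the pairing were counted in each comparison, too few for a share under 0.05. They were swaps of DEX within pairs, of the lines for the line difference, and of the lines within replicates for the difference of responses. Of these, 1 of 16 reached the real 236 with the VND7 fusion (highest other 0), 1 of 16 the real 162 with the empty vector (highest other 1), 1 of 16 the real 239 for the difference (highest other 0) and 1 of 16 the real 21 between lines (highest other 2). For the difference, swaps of DEX within pairs of each line separately also keep the pairing. Among those drawn, the highest called 253, above the real 239, and the next 101. The highest swapped every empty-vector pair and no VND7 fusion pair, which turns the difference into the sum of both responses. Such swaps test for a response in either line, so they cannot decide on the difference.

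The first pattern weighed is the rise of 64 probe sets with DEX in the empty-vector line, 63 of which did not pass in the other line. DEX acting on these genes in any line was argued against: in replicates held out of the selection, their median log2 change with the VND7 fusion was -0.23 to -0.058, and the test needed at least 50% of the change in the empty-vector line. A single aberrant replicate was also argued against, since the held-out median in the empty-vector line was 1.288 at its lowest (2.28 at its highest). What stays open, untested, is an action of the VP16-GR protein or of the insertion in that line, which may differ from that of the fusion with VND7.

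The second pattern is the higher level without DEX, in the VND7 fusion line, of probe sets that DEX raised there. A general shift between the lines could not have appeared, since each array is divided by its own median. A shift tied to signal was argued against: 100% of 10000 random sets matched on signal had a median below the observed 0.26 (highest 0.093). Probe sets are not independent, so that share is not a p-value. Some activity of the fusion protein without DEX is a candidate explanation, with a held-out median line difference of 0.338 to 0.442 over the 5 replicates. A shift of DEX-raised probe sets in general stays open: those raised in the empty-vector line had held-out medians of 0.004 to 0.295 (all probe sets -0.029 to 0.042; in replicate 3 the set's 0.004 was below their 0.033), which were under those of the VND7 fusion set in 5 of 5 replicates but under 50% of them in 3. The pattern was found and tested on the same data, and an effect of the insertion or of the line's growth stays open.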

How the results depend on the processing

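The alternatives chosen after the data were seen were the 10th-percentile pseudocount, the recovered MAS5 scaling, the batch term, and the replicate block with the dim-probe filter; the others were planned. With the replicate block, which pairs same-numbered arrays, the counts were 236 for the DEX response with the VND7 fusion (103 without it), 162 with the empty vector (64), 239 for the difference of responses (89), 21 for the lines under CHX alone (6), 84 for the induced set (45) and 5 for calls shared between the lines (1). With a batch term they were 234, 159, 236, 20, 83 and 6. With array weights 2 calls were shared. The block with the dim-probe filter (13647 probe sets) gave 217, 155, 218 and 22, with 8 calls shared between the lines (Fisher's exact p = 0.03315 for the rises alone). These terms remove differences between batches from the spread. Beside the calls named with it above, the block changed no other call of a named gene or fixed list.

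With an estimated inter-gene correlation 0 lists passed in place of 1; the adjusted p of lignin genes was 0.000512 to 0.0269 over other settings and 0.00331 to 0.117 with single arrays left out. Excluding empty-vector calls without the test of the difference gave an induced set of 81, since fewer criteria apply. With each array left out in turn, counts ranged from 64 (without VND7_DEX_CHX replicate 1; 67 without replicate 3) to 107 with the VND7 fusion, 52 to 65 with the empty vector, 69 to 100 for the difference, 5 to 8 for the lines, 36 to 58 for the induced set, 1 to 2 for shared calls (2 without VND7_CHX replicate 1) and 0 to 1 for lists (0 without VND7_DEX_CHX replicate 2 or 3 or VND7_CHX replicate 1). The cause was not tested, and the fits with an array left out had no replicate block. All other settings kept each count within 1.5 times. The robust variance has no list test, as camera has no such option.

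For named genes 0 results reversed. With single arrays left out 787 kept their side of the threshold and 53 lost a call, and with other settings 941 kept it and 3 lost a call: AT5G44630 in the difference with the 30th-percentile pseudocount (adjusted p = 0.0552; 0.000827 to 0.0552 over all alternatives), and AT1G23460 between lines without the variance trend and with the MAS5 scaling. Low signals limit what can be seen: the pseudocount took the difference for AT5G44630 from 4.51 to 0.61.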

Other observations

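The genes in this part were chosen after their values had been seen. The lists and their tests were added after the data had been opened and before any test was run. With the VND7 fusion DEX raised further genes, outside the rule for named genes. The serine carboxypeptidase-like genes scpl20 and scpl48 rose by 2.00 ± 0.23 and 1.52 ± 0.24 on the log2 scale (limma, adjusted p = 4.457e-05 and 0.001708), the subtilase SBTI1.1 by 1.77 ± 0.27 (0.001021) and the xylanase family gene AT4G08160 by 1.04 ± 0.23 (0.04732). TBL34, of the family of wall O-acetyltransferases, rose by 1.85 ± 0.30 (0.002531), and AT5G26330 and AT3G27200, of the cupredoxin family, by 2.01 ± 0.29 and 1.91 ± 0.32 (0.0006857 and 0.003711). AT4G28650, a receptor kinase related to PXY of the procambium, rose by 2.05 ± 0.29 (0.0005669). Each was higher in 5 of 5 pairs, which selection on these same arrays favours. The difference between the lines' responses did not pass for TBL34 (0.1947), AT4G08160 (0.1182) and AT3G27200 (0.08002) except with the block (0.006393, 0.01593 and 1.469e-05), and passed for the other 5 (0.002346 to 0.03878). In the empty-vector line the class III peroxidase genes AT3G01190, AT5G17820 and AT5G64100 rose by 2.02 ± 0.22, 1.43 ± 0.20 and 1.26 ± 0.20 (2.379e-05, 0.0007918 and 0.002056), with changes of -0.21, -0.21 and -0.49 with the VND7 fusion and a difference that passed for each (0.0005381, 0.006476 and 0.002862). None of these is in the added list of class III peroxidases, which was made from gene symbols and had 0 of 6 members past the threshold in that line (limma; camera adjusted p = 0.6519). With the block the fall of AT5G64100 with the VND7 fusion passed too (0.02401). Also in the empty-vector line, the auxin-related genes HAT2 and GH3.17 rose by 1.30 ± 0.14 and 1.91 ± 0.27 (2.379e-05 and 0.0008137), and LEP, an AP2/ERF gene, by 1.78 ± 0.18 (1.618e-05). HAT2 changed by -0.23 with the VND7 fusion, and its difference between the lines passed (limma, adjusted p = 0.0002814).

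A list of 30 xylem loci recalled from background knowledge, 23 of them measured, had 8 members up with the VND7 fusion (9 adjusted over the list alone, 9 with the block), a median of 0.68 and medians of 1.00, 0.99 and 0.52 within batches (camera adjusted p = 1.322e-27; adjusted p = 2.013e-06 with an estimated correlation; 3.874e-07 by fry). It was compiled with the data in hand and can hold genes known as VND7 targets, so it is not independent evidence. In the difference 3 passed (7 adjusted over the list alone; 1.895e-17; 4.194e-05 with an estimated correlation), and in the empty-vector line 0 passed (limma; median -0.09; camera adjusted p = 0.5524). Serine carboxypeptidase-like genes (29) were higher in the difference (adjusted p = 0.004925; adjusted p = 0.06602 with an estimated correlation; 0.1112 by fry; 0.006463 with the block), with 2 members past the threshold and medians of 0.32, 0.18 and 0.01 within batches. Plastid-encoded genes (69) shifted upwards in the empty-vector line by a median of 0.13 (0.0104; adjusted p = 0.6954 with an estimated correlation; 0.717 by fry; 2.08e-05 with the block) with 0 members past the threshold, and medians of 0.25, 0.07 and 0.08 within batches. With the VND7 fusion their median was 0.10, and they did not pass by camera (adjusted p = 0.05869) except with the block (0.0001068). With an estimated correlation the camera adjusted p was 0.9746, and by fry it was 0.9964. The within-batch medians of -0.28, 0.28 and 0.10 differed in sign. Xyloglucan endotransglucosylase genes (10) had a median of -0.25 with the VND7 fusion and did not pass (0.08795; adjusted p = 0.5362 with an estimated correlation) except with the block (0.004064), with medians of -0.51, -0.15 and -0.18 within batches. Of the 21 added lists, the remaining 18 did not pass with the VND7 fusion with or without the block.

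The unnamed probe set with the largest line difference was at 3870 or more on every array of the VND7 fusion line and at 45.6 or less on every empty-vector array, and moved by -0.06 ± 0.25 on the log2 scale with DEX in the VND7 fusion line.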
